A study of Arabidopsis thaliana with 9 samples.

How the data were processed

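The data were mRNA-seq values of 9 libraries of whole seedlings of Arabidopsis thaliana, 3 each of Col-0, cyp71-3 and se-1, grouped by the genotype in the labels. Per the labels' protocols, total RNA was extracted with TRIzol, mRNA was enriched on capture beads, fragmented, converted to cDNA, ligated to adapters, amplified by PCR and sequenced on an Illumina platform. Bead capture of mRNA and purification of ligated products disfavour short and non-polyadenylated RNAs, such as small nuclear RNAs. Values of other genes annotated as short, such as miRNA precursor genes, may also rest on few molecules. The design text also names the allele cyp71-2 and small RNA sequencing, which are not analysed here.

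The deposited values are FPKM per gene, 1 file per library with 2 decimals. Per the submitters' processing notes, Trim Galore 0.6.7, STAR 2.7.2b, Cuffnorm, Cuffdiff and the TAIR10 build were used. The role of each, the annotation, the strandedness and the library scaling are not given in the sources used here. FPKM divides by transcript length and by library total, so a change in a few abundant genes shifts all others, and fragments shared by similar copies or by overlapping genes on opposite strands may be divided between them in a way the values do not show. Symbols, annotated lengths, gene types and process terms came from the TAIR10.1 reference annotation, matched by locus identifier for 32538 of 32823 genes. Its coordinates were not used in the text.

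The deposited FPKM values are not counts. Their lowest steps in single-transcript genes implied relative depths up to 1.59 times that of the shallowest library. Whole fragments were not recovered from them because values are rounded and effective lengths are not known, so no count model was run. The chloroplast genome held 0.0313% to 3.44% of the FPKM sum of a library, the highest in cyp71-3 replicate 1, 1.96% in Col-0 replicate 2 and 1.87% in se-1 replicate 1. In 22 genes of at most 180 bp, more than 50 FPKM were listed in 1 or 2 libraries and 0 in the others. No library was identical to another.

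Tests were run on log2(FPKM + 1) for 19180 genes with a mean FPKM over all libraries of at least 1. A linear model with the 3 genotypes was fitted to all 9 libraries with limma 3.58.1 in R 4.3.3, with moderated variances and an intensity trend, leaving 6 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05, two-sided, were called. Gene lists were tested with limma's camera with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Of the called lists, phosphate starvation in cyp71-3 against Col-0 was the only one also called with an estimated correlation. The 21 lists with 427 members, the design and the rule for named genes were fixed before the data were examined. All members were in the files, and 418 carried the listed symbol in the reference. Median, mean and camera's direction differed in sign only for lists that were not called: in cyp71-3 against Col-0 for precursor, machinery, flowering, salicylate and stomatal genes, in se-1 against Col-0 for machinery, jasmonate, auxin and phosphate starvation genes, and between the mutants for machinery and stomatal genes. Except where another count is given, counts adjusted over the list alone differed by at most 1 gene per direction from those over all genes tested.

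The rule named CYP71 and SE, then, for each mutant against Col-0, the 6 largest rises and 6 largest falls among called genes with a symbol whose groups did not overlap, and 4 each way between the mutants. It added the 4 largest called miRNA targets each way, 2 each way from the precursor, tasiRNA and machinery lists, and 2 from every other list with at least 3 called members. Of these, the text gives those that carry each comparison. Genes with groups that did not overlap numbered 13445, 10868 and 12699 in the 3 comparisons (70.1%, 56.7% and 66.2%), where chance gives 10%.

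The procedure was tested on simulated data with the spread of the real libraries and 200 changed genes among 19180, for cyp71-3 against Col-0. It recovered 36% of genes changed by 0.25 on the log2 scale, 82% at 0.5 and 100% at 1 and at 2, with 7 false calls. The real comparison called 12148 genes, so its cut-off on the unadjusted p was looser. The simulated recovery and number of false calls therefore do not carry over to it. Overlap between mutants was set beside 100 simulations without effect that shared the Col-0 libraries. Alternatives were other pseudocounts, filters, scalings, variance settings, library weights, a replicate block, a threshold on fold change leaving out each library and dividing the Col-0 libraries between the mutants. Summaries and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.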

Results

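Whole Arabidopsis thaliana seedlings were collected at 2 weeks of age under long days, and their mRNA was captured on beads and sequenced. The 9 libraries came from 3 genotypes with 3 libraries each: the wild-type accession Col-0, the mutant cyp71-3 and the mutant se-1. CYP71 is a cyclophilin, a peptidyl-prolyl isomerase with WD40 repeats, and SE (SERRATE) is a zinc-finger protein required for processing of microRNA (miRNA) precursors. The design text asks what loss of CYP71 does to miRNA target expression. The files gave FPKM values for 32823 genes, of which 19180 with a mean FPKM of at least 1 were tested. Library values summed to between 825340 and 937140 FPKM, and the steps between the lowest values implied depths up to 1.59 times that of the shallowest library. Libraries of one genotype correlated with each other at r of at least 0.982 across genes, against 0.931 to 0.963 between genotypes. Values below are mean FPKM ± SD of the 3 libraries of a genotype, and fold changes with their SE are on the log2(FPKM + 1) scale, which understates changes of low genes. The labels do not say that the libraries came from separate plant cultures, so p-values measure the spread between these samples.

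The targeted genes were examined first. CYP71 (AT3G44600, chromosome 3) stood at 17.9 ± 1.13 FPKM in Col-0, 4.09 ± 0.36 in cyp71-3 and 17.8 ± 0.65 in se-1. It was 4.37-fold lower in cyp71-3 than in Col-0 (limma adjusted p = 1.63e-09), and lower in each of the 3 libraries. SE (AT2G27100, chromosome 2) was at 31.7 ± 1.37 FPKM in Col-0, 33.1 ± 0.22 in cyp71-3 and 27.2 ± 1.73 in se-1. The fall of SE in se-1 was 1.16-fold (limma adjusted p = 0.0052), and the value in cyp71-3 did not differ from Col-0 (limma adjusted p = 0.326).

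**Figure D1:**
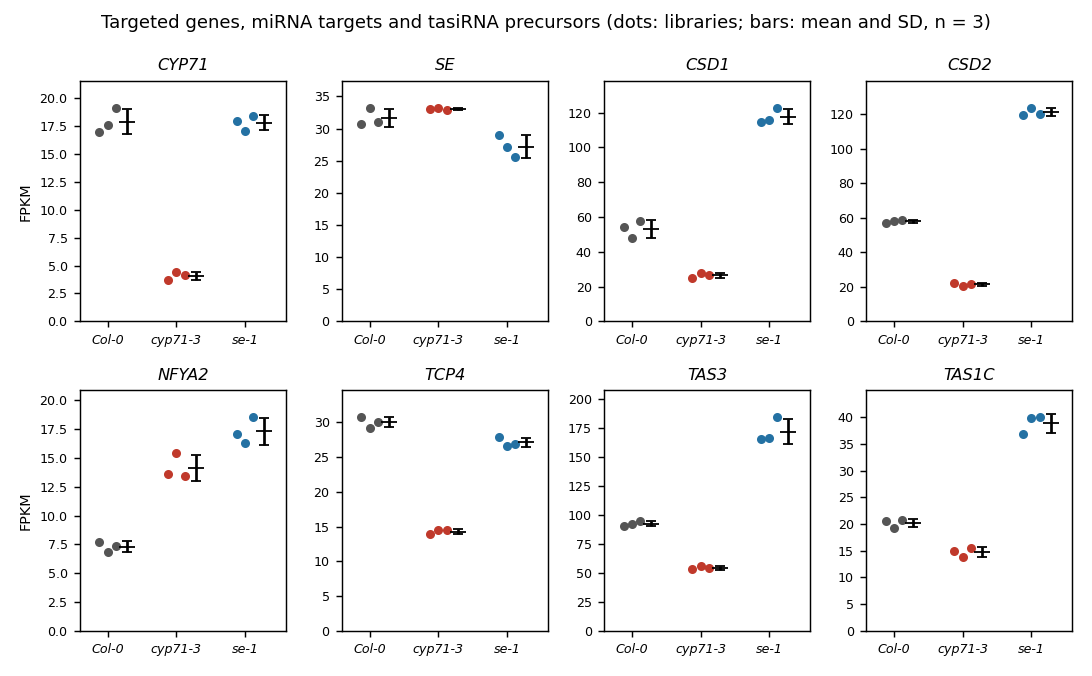
FPKM (vertical axes, from 0) of CYP71, SE, 4 miRNA targets and 2 tasiRNA precursors in each library of Col-0, cyp71-3 and se-1; dots are libraries and bars give mean and SD, n = 3. CSD1, CSD2, TAS3 and TAS1C lay below Col-0 in cyp71-3 and above it in se-1, with CSD2 at 58.0, 21.5 and 121 FPKM.

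The first comparison, cyp71-3 with Col-0, asked how miRNA targets and other genes responded to loss of CYP71. In cyp71-3, genes of anthocyanin synthesis, the cell cycle, the phosphate starvation response and cold and abscisic acid (ABA) responses were mostly higher than in Col-0, while miRNA targets moved in both directions. Of these 4 list calls, only that of phosphate starvation held with an estimated correlation between genes (adjusted p = 0.0474). DFR (AT5G42800), which reduces dihydroflavonols on the way to anthocyanins, rose 15.9-fold, from 10.2 ± 0.55 to 162 ± 3.42 FPKM. CYCB1;1 (AT4G37490), a mitotic cyclin, rose 4.59-fold, and the phosphatase gene PS2 (AT1G73010) rose 5.19-fold. Of the miRNA targets, the copper/zinc superoxide dismutase genes CSD1 and CSD2 fell from 53.2 ± 5.04 and 58.0 ± 0.77 FPKM to 26.5 ± 1.56 and 21.5 ± 1.03, while NFYA10 rose 3.46-fold. The test called 12148 of 19180 genes, 5871 higher and 6277 lower, and 1263 of them differed by at least 1 on the log2 scale (677 higher, 586 lower).

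Of 87 listed miRNA targets, 78 were tested in cyp71-3. Of these, 28 were higher, 30 lower and 20 did not pass (28 higher and 31 lower adjusted over the list alone), with a median log2 fold change of -0.09. All 19180 tested genes also moved both ways, with 63.3% called, 5871 higher and 6277 lower. Movement in both directions is therefore not particular to miRNA targets. The list as a whole was not called (camera adjusted p = 0.785), although fry, which asks whether the members move on balance one way, gave a fall (adjusted p = 0.00103). Unlike camera, fry does not set a list against the other genes. In cyp71-3 it passed every list tested except precursor and machinery genes, so its result is not particular to miRNA targets. Under quantile normalization the median of miRNA targets was -0.01. The largest rises were those of NFYA10 (AT5G06510, 1.45 ± 0.11 SE), GRF1 (AT2G22840, 1.06 ± 0.09), NFYA5 (AT1G54160, 0.96 ± 0.12) and NFYA2 (AT3G05690, 0.87 ± 0.07), all transcription factor genes, targeted by miR169 or, for GRF1, by miR396. The largest falls were those of CSD2 (AT2G28190, -1.39 ± 0.04), TCP4 (AT3G15030, -1.02 ± 0.04), a leaf development regulator targeted by miR319, CSD1 (AT1G08830, -0.98 ± 0.07) and SNZ (AT2G39250, -0.97 ± 0.07), an AP2-like repressor of flowering targeted by miR172. Of the 8 precursors and targets of trans-acting siRNAs (tasiRNAs), 5 were lower and 1 higher in cyp71-3, and the list was not called (camera adjusted p = 0.0845). The precursor TAS3 (AT3G17185) fell from 92.3 ± 2.18 to 54.3 ± 1.43 FPKM and TAS1B (AT1G50055) from 16.8 ± 1.85 to 7.03 ± 0.42, while ARF3 (AT2G33860), an auxin response factor gene targeted by TAS3-derived siRNAs, rose 1.33-fold. ARF3 was higher in se-1 as well (18.24 to 19.69 FPKM, against 12.13 to 12.34 in Col-0), where TAS3 rose. ARF2, also on this list, was at 70.43 to 71.71 FPKM in cyp71-3 and 85.34 to 86.62 in Col-0.

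Precursor genes of miRNAs were measured poorly, since 23 of 29 listed were at 0 in every library and 27 were annotated as shorter than 300 bp. The 6 tested were not called as a list in cyp71-3 (camera adjusted p = 0.87). Of these, MIR163 (AT1G66725) fell from 27.9 ± 4.70 to 7.33 ± 1.61 FPKM, MIR824A (AT4G24415) fell 1.62-fold, and MIR408 (AT2G47015) rose, from 0, 0 and 14.28 to 13.90, 19.74 and 14.60 FPKM. MIR157c (AT3G18217), outside that list but among the largest rises, was listed at 0 in the Col-0 libraries and at 23.92, 13.61 and 7.55 FPKM in cyp71-3. Of 24 genes of the miRNA machinery, 4 were higher and 6 lower, by less than 1 on the log2 scale. These included NOT2A (AT1G07705, 0.50 ± 0.06) and HST (AT3G05040, 0.37 ± 0.09) upward and CPL1 (AT4G21670, -0.44 ± 0.07) and NOT2B (AT5G59710, -0.35 ± 0.05) downward.

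Outside the miRNA pathway, 22 of 25 cell cycle genes were higher in cyp71-3 and none lower (median 0.91, camera adjusted p = 2.51e-08, but adjusted p = 0.0562 with an estimated correlation). CYCB1;1 rose from 3.16 ± 0.28 to 14.5 ± 0.99 FPKM and CYCB2;3 (AT1G20610) 3.57-fold. All 10 phosphate starvation genes were higher (median 1.06, camera adjusted p = 9.58e-06, and adjusted p = 0.0474 with an estimated correlation), among them PS2 (8.88 ± 1.14 to 46.1 ± 0.82 FPKM) and the non-coding RNA gene AT4 (AT5G03545, 3.64-fold). Of 18 flavonoid and anthocyanin genes, 12 were higher and 4 lower (median 1.54, camera adjusted p = 0.000486, adjusted p = 0.126 with an estimated correlation). UF3GT (AT5G54060), a glycosyltransferase gene, rose from 1.19 ± 0.14 to 30.4 ± 0.61 FPKM. In the cold and ABA list, 14 of 16 were higher and 1 lower (median 0.80, camera adjusted p = 9.58e-06, adjusted p = 0.113 with an estimated correlation), among them the lipid transfer protein genes LTP4 (AT5G59310, 1.02 ± 0.76 to 17.7 ± 1.15 FPKM) and LTP3 (AT5G59320, 7.93-fold). Of 10 heat shock genes, 6 were lower and 1 higher (camera adjusted p = 0.0104, adjusted p = 0.235 with an estimated correlation), with the chaperone genes HSP70-4 (AT3G12580) down 4.13-fold and HSP90.1 (AT5G52640) down 3.02-fold. Of 27 photosynthesis genes, 20 were lower and none higher (median -0.25, camera adjusted p = 0.000147, adjusted p = 0.578 with an estimated correlation). Under quantile normalization the median turned to 0.02 (camera adjusted p = 0.959), while median centring kept the call (median -0.26, camera adjusted p = 0.000251). Quantile normalization equalizes the highest values of the libraries, where these genes lie, so it cannot tell a fall from scaling. RCA (AT2G39730), the Rubisco activase gene, was at 8269 ± 98.0 FPKM in Col-0 and 5334 ± 88.9 in cyp71-3 as deposited.

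The remaining lists were not called in cyp71-3, although most of their members were. Of all genes tested, 63.3% were called in this comparison, so many called members do not set a list apart. Of 12 iron deficiency genes, 9 were lower, among them the ubiquitin ligase gene BTS (AT3G18290, 2.33-fold), and 3 higher, among them the root ferric reductase gene FRO2 (AT1G01580, 2.92-fold; camera adjusted p = 0.0832). Salicylate defence genes divided into 5 higher and 7 lower of 17, with the pathogenesis-related gene PR1 (AT2G14610) down 12.3-fold and the lipase-like gene SAG101 (AT5G14930) up 2.57-fold. Jasmonate genes divided into 9 higher and 9 lower of 21, including a 5.28-fold rise of AOC2 (AT3G25770), which acts in jasmonate synthesis. Of 14 circadian clock genes, 5 were higher and 7 lower, with the morning gene CCA1 (AT2G46830) down 3.00-fold and LNK2 (AT3G54500) down 2.69-fold. Auxin early response genes were lower for 6 of 10 and higher for 1, with IAA1 (AT4G14560) and IAA4 (AT5G43700) down 1.78-fold and 1.75-fold. Flowering and homeotic regulators were 5 higher and 5 lower of 11, aliphatic glucosinolate genes 7 higher and 2 lower of 15, and copper deficiency genes 4 higher and 3 lower of 7. Under quantile normalization the aliphatic glucosinolate list was called higher (median 0.20, camera adjusted p = 0.0101, against 0.12 and 0.106 as deposited). With an estimated correlation, run only on the values as deposited, its camera adjusted p was 0.529. FLC (AT5G10140), a repressor of flowering, was at 2.81 ± 0.74 FPKM in Col-0 and at 0.07, 0 and 0 in the cyp71-3 libraries. Among the lists that stand for organs and cell types, root markers were 8 higher and 5 lower of 17 and stomatal lineage genes 3 higher and 4 lower of 9. Of 15 seed maturation genes, 1 was expressed highly enough to be tested: EM6 (AT2G40170), named after its values were seen, rose from 0.49 ± 0.24 to 3.88 ± 0.54 FPKM. The median and mean differed in sign for flowering and homeotic regulators (0.31 and -0.26, test lower) and salicylate defence (0.01 and -0.24, test lower).

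The largest changes among named genes in cyp71-3 included 2 further rises, of NUDT24 (AT5G19470), a Nudix hydrolase gene, from 0.07 ± 0.03 to 20.5 ± 0.33 FPKM, and of NAC044 (AT3G01600), a NAC transcription factor gene, from 0.63 ± 0.31 to 25.0 ± 0.85. LDOX (AT4G22880), which follows DFR in anthocyanin synthesis, rose 15.4-fold. Among the falls, the major latex protein-like genes MLP328 (AT2G01520) and MLP329 (AT2G01530) went from 126 ± 3.41 and 72.6 ± 3.03 FPKM to 5.58 ± 0.73 and 3.88 ± 0.16. AIR1 (AT4G12550), an auxin-induced gene of root cultures, fell 13.8-fold, RL6 (AT1G75250), a MYB-related gene, 14.2-fold, and TPX2 (AT1G65970), a thioredoxin-dependent peroxidase gene, 7.23-fold. Similar copies such as MLP328 and MLP329 may share fragments, and the files do not show how those were divided.

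**Figure D2:**
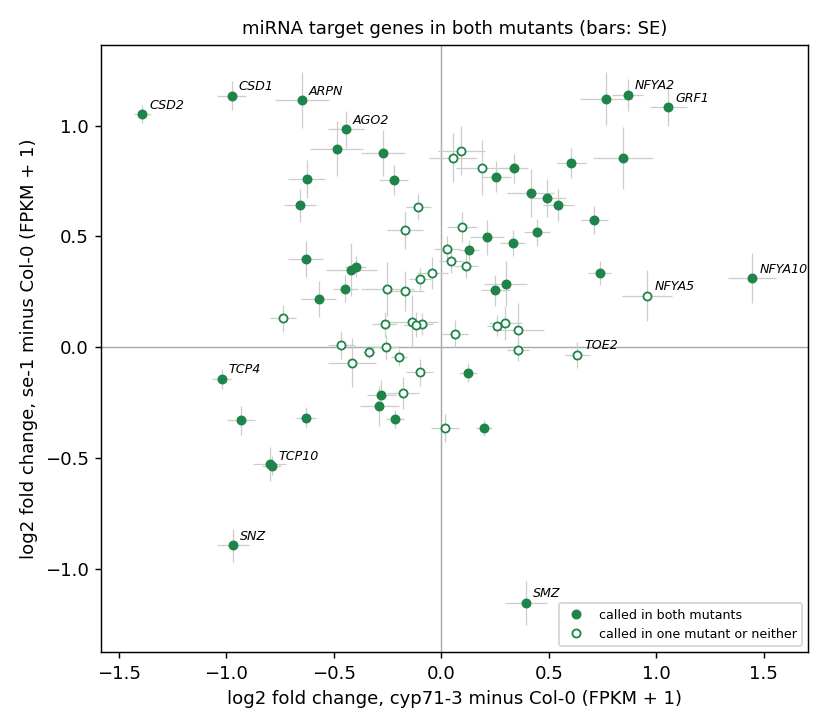
Log2 fold change of the 78 tested miRNA targets in cyp71-3 (horizontal) and in se-1 (vertical) against the same Col-0 libraries, on the log2(FPKM + 1) scale, with SE bars; filled points were called in both mutants. Of the points called in both, 19 were higher in both, 9 lower in both, 14 lower in cyp71-3 and higher in se-1, and 3 the opposite.

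The second comparison, se-1 with Col-0, gave the response of the same genes to a mutation in SE. In se-1, miRNA targets were mostly higher than in Col-0, and salicylate defence genes were mostly lower, although neither list call held with an estimated correlation (adjusted p = 0.0726 and 0.0559). CSD1 and CSD2, which fell in cyp71-3, rose 2.21-fold and 2.09-fold, to 118 ± 4.42 and 121 ± 2.15 FPKM. TAS3 rose 1.86-fold, to 172 ± 10.8 FPKM. PR1 fell 38.2-fold, from 49.0 ± 0.38 to 1.28 ± 0.19 FPKM. The test called 9633 of 19180 genes, 4818 higher and 4815 lower, and 675 of them differed by at least 1 on the log2 scale (386 higher, 289 lower).

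Of the 78 tested miRNA targets, 45 were higher in se-1, 14 lower and 19 did not pass, with the same counts adjusted over the list alone. Their median log2 fold change was 0.31 (camera adjusted p = 5.63e-05, adjusted p = 0.0726 with an estimated correlation). The largest rises were those of NFYA2 (1.14 ± 0.07 SE), CSD1 (1.14 ± 0.07), CUC1 (AT3G15170, 1.12 ± 0.12), an organ boundary gene targeted by miR164, and ARPN (AT2G02850, 1.12 ± 0.13), a plantacyanin gene targeted by miR408. The largest falls were those of SMZ (AT3G54990, -1.15 ± 0.10) and SNZ (-0.89 ± 0.07), both targeted by miR172, TCP10 (AT2G31070, -0.53 ± 0.04), targeted by miR319, and HAM3 (AT4G00150, -0.53 ± 0.08), targeted by miR171. Of the 8 tasiRNA precursors and targets, 4 were higher and 3 lower (camera adjusted p = 0.359): TAS1C (AT2G39675) rose 1.93-fold, and TAS2 (AT2G39681) and ARF2 (AT5G62000) fell 1.48-fold and 1.43-fold.

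Among miRNA precursor genes in se-1, MIR824A rose from 4.03 ± 0.70 to 12.6 ± 1.01 FPKM, MIR408 stood at 20.21, 32.22 and 27.98 FPKM, and MIR163 fell to 4.24 ± 2.61. MIR157c, listed at 0 in Col-0, was at 146.03, 139.42 and 96.20 FPKM. The small nuclear RNA genes U4.8 (AT5G04305) and U4.5 (AT5G04085), also listed at 0 in Col-0, were at 366.86 to 546.38 and at 202.07 to 301.99 FPKM, and U12 (AT1G61275) was called higher in se-1 as well. These 3 genes are annotated at 149, 153 and 175 bp, and in cyp71-3 replicate 2 all were listed at 0 while U4.8 reached 1298.08 FPKM in replicate 1. Of 24 genes of the miRNA machinery, 2 were higher and 4 lower, with NOT2B up 2.07-fold, CPL1 up 1.29-fold and STA1 (AT4G03430) down 1.33-fold.

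Of 17 salicylate defence genes, 13 were lower in se-1 and 2 higher (median -0.65, camera adjusted p = 5.63e-05, adjusted p = 0.0559 with an estimated correlation). Beside PR1, the salicylate synthesis gene PBS3 (AT5G13320) fell from 6.57 ± 0.30 to 0.67 ± 0.11 FPKM. Cell cycle genes were higher for 17 of 25 and lower for none (median 0.35, camera adjusted p = 7.78e-05, adjusted p = 0.161 with an estimated correlation), among them CYCB2;3 (2.15-fold) and PCNA1 (AT1G07370, 1.66-fold), a clamp of DNA replication. Photosynthesis genes were lower for 23 of 27 and higher for none (median -0.24, camera adjusted p = 1.4e-07, adjusted p = 0.495 with an estimated correlation). Under quantile normalization the median was -0.02 and the call ended (camera adjusted p = 0.753), while median centring kept it (median -0.25, camera adjusted p = 6.21e-07). Heat shock genes were lower for 7 of 10 and higher for 1. That list was not called (camera adjusted p = 0.0565), and it passed without Col-0 replicate 3 (adjusted p = 0.0382), cyp71-3 replicate 3 (0.0464) or se-1 replicate 2 (0.0387).

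The other lists were not called in se-1. Cold and ABA genes were 10 higher and 3 lower of 16, with KIN1 (AT5G15960) up 2.76-fold and LTP3 up 2.91-fold, and root markers 10 higher and 4 lower of 17, with the iron transporter gene IRT1 (AT4G19690) up 4.43-fold and PRP1 (AT1G54970) up 5.72-fold. Of 18 flavonoid and anthocyanin genes, 8 were lower and 2 higher, and UF3GT fell to 0.39 ± 0.04 FPKM. Jasmonate genes were 8 higher and 6 lower of 21, with AOC2 up 3.80-fold and the defensin gene PDF1.2B (AT2G26020) down 16.4-fold. Aliphatic glucosinolate genes were 4 higher and 7 lower of 15, with CYP79F2 (AT1G16400) down 2.74-fold. Iron deficiency genes were 7 higher and 3 lower of 12, phosphate starvation genes 4 higher and 3 lower of 10, and copper deficiency genes 0 higher and 4 lower of 7. Circadian clock genes were 4 higher and 7 lower of 14, with CCA1 down 2.08-fold, and auxin early response genes 4 higher and 3 lower of 10, with GH3.3 (AT2G23170) up 2.01-fold. Of 11 flowering and homeotic regulators, 3 were higher, including the homeobox gene KNAT2 (AT1G70510, 5.42-fold), and 3 lower, including FLC (11.7-fold). Stomatal lineage genes were 3 higher and 3 lower of 9, with FAMA (AT3G24140), which acts in guard cell formation, down 1.55-fold.

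The largest changes among named genes in se-1 also included a rise of MRN1 (AT5G42600), a marneral synthase gene, from 0.16 ± 0.04 to 8.50 ± 0.54 FPKM. SAG13 (AT2G29350), a senescence-associated gene, fell 24.0-fold, PCR1 (AT1G14880), a cadmium resistance gene, 40.0-fold, and PP2-A1 (AT4G19840), a phloem lectin gene, 8.06-fold.

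**Figure D3:**
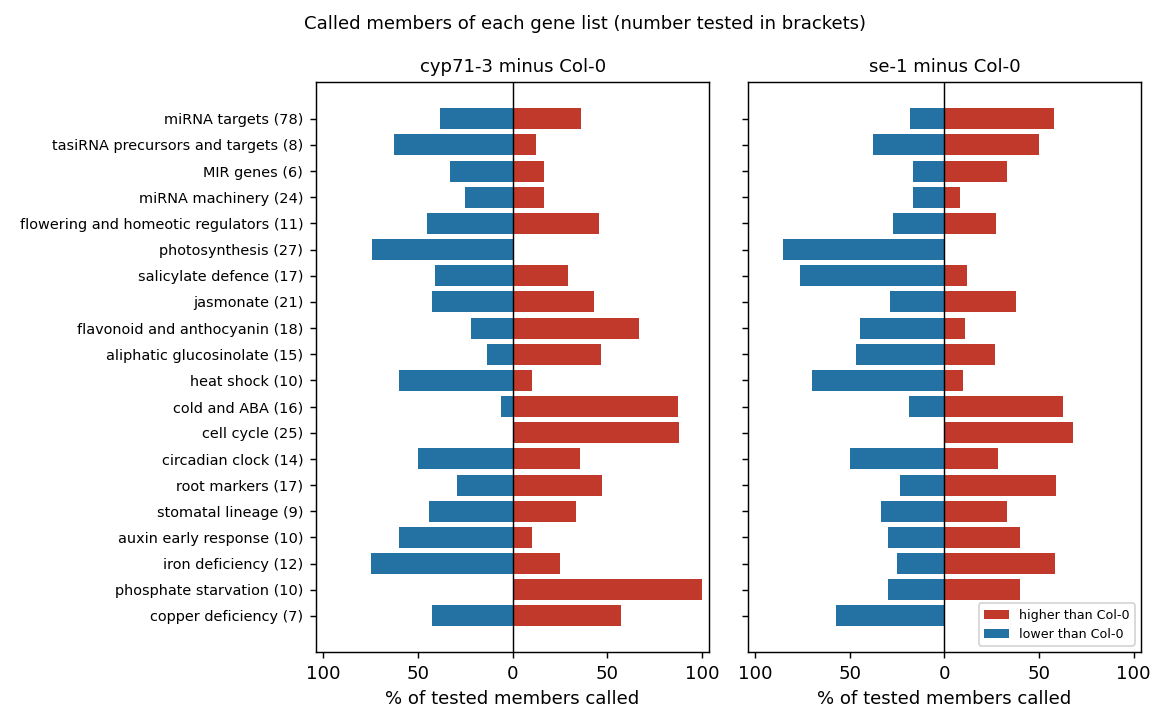
Share of tested members of each gene list called higher (red, right) or lower (blue, left) than Col-0, in percent, in cyp71-3 and se-1, with the number tested in brackets. All 10 phosphate starvation genes were higher in cyp71-3, against 4 higher and 3 lower in se-1. Of the 27 photosynthesis genes, 20 were called lower in cyp71-3 and 23 in se-1 as deposited. The median log2 fold change of all 27 was 0.02 in cyp71-3 and -0.02 in se-1 under quantile normalization. Under median centring it was -0.26 in cyp71-3 and -0.25 in se-1.

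The third comparison set the mutants against each other, which tests the difference between their effects. It does not use the Col-0 means, although the Col-0 libraries entered the variances and the filter. miRNA targets were mostly lower in cyp71-3 than in se-1, and TAS3 and TAS1C were lower, while more anthocyanin, phosphate starvation, salicylate defence, cold and ABA and cell cycle genes were higher than lower. None of these list calls held with an estimated correlation (adjusted p = 0.0523 to 0.226). CSD2 stood 5.63-fold and CSD1 4.44-fold lower in cyp71-3, and TAS3 3.17-fold lower. DFR was 15.3-fold and PBS3 8.24-fold higher in cyp71-3. The test called 11921 genes, 5749 higher and 6172 lower in cyp71-3, and 1410 differed by at least 1 on the log2 scale (630 higher, 780 lower).

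Of the 78 miRNA targets, 49 were lower in cyp71-3 than in se-1 and 11 higher (50 and 13 adjusted over the list alone), with a median of -0.28 (camera adjusted p = 0.000256, adjusted p = 0.0523 with an estimated correlation). The largest differences downward were those of CSD2 (-2.44 ± 0.04 SE), CSD1 (-2.11 ± 0.07), ARPN (-1.76 ± 0.13) and AGO2 (AT1G31280, -1.43 ± 0.08), an Argonaute gene targeted by miR403. Upward they were those of SMZ (1.55 ± 0.10), NFYA10 (1.13 ± 0.11), NFYA5 (0.73 ± 0.12) and TOE2 (AT5G60120, 0.67 ± 0.06). Of the 8 tasiRNA precursors and targets, 6 were lower and 1 higher (camera adjusted p = 0.0199, adjusted p = 0.131 with an estimated correlation), and MIR824A was 5.06-fold lower.

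Of the other lists, phosphate starvation genes (9 of 10 higher, 1 lower; camera adjusted p = 0.000223), flavonoid and anthocyanin genes (14 of 18 higher, 3 lower; adjusted p = 3.81e-05) and salicylate defence genes (13 of 17 higher, 1 lower; adjusted p = 0.00053) were called higher in cyp71-3. With an estimated correlation each had an adjusted p = 0.0523. IPS1 (AT3G09922), a non-coding RNA gene induced by phosphate starvation, was at 16.8 ± 1.37 FPKM in cyp71-3 and 1.15 ± 0.43 in se-1, and FMO1 (AT1G19250), a gene of systemic defence, at 3.41 ± 0.18 and 0.35 ± 0.24. Cold and ABA genes (10 of 16 higher, 3 lower; adjusted p = 0.0029), aliphatic glucosinolate genes (11 of 15 higher, 3 lower; adjusted p = 0.00681) and cell cycle genes (14 of 25 higher, 7 lower; adjusted p = 0.0133) were called higher as well. Iron deficiency genes were called lower (9 of 12 lower, 3 higher; adjusted p = 0.0133). None of those 4 calls held with an estimated correlation (adjusted p = 0.18, 0.222, 0.226 and 0.131). CYP79F1 (AT1G16410), of glucosinolate synthesis, was 2.51-fold higher in cyp71-3, CYCB2;2 (AT4G35620) 2.81-fold higher, and BHLH101 (AT5G04150), an iron deficiency regulator, 3.08-fold lower. Beyond these lists, the cytochrome P450 gene CYP71A12 (AT2G30750), unrelated to CYP71, was 43.0-fold higher, and BT2 (AT3G48360), a BTB protein gene, 15.4-fold lower.

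**Figure D4:**
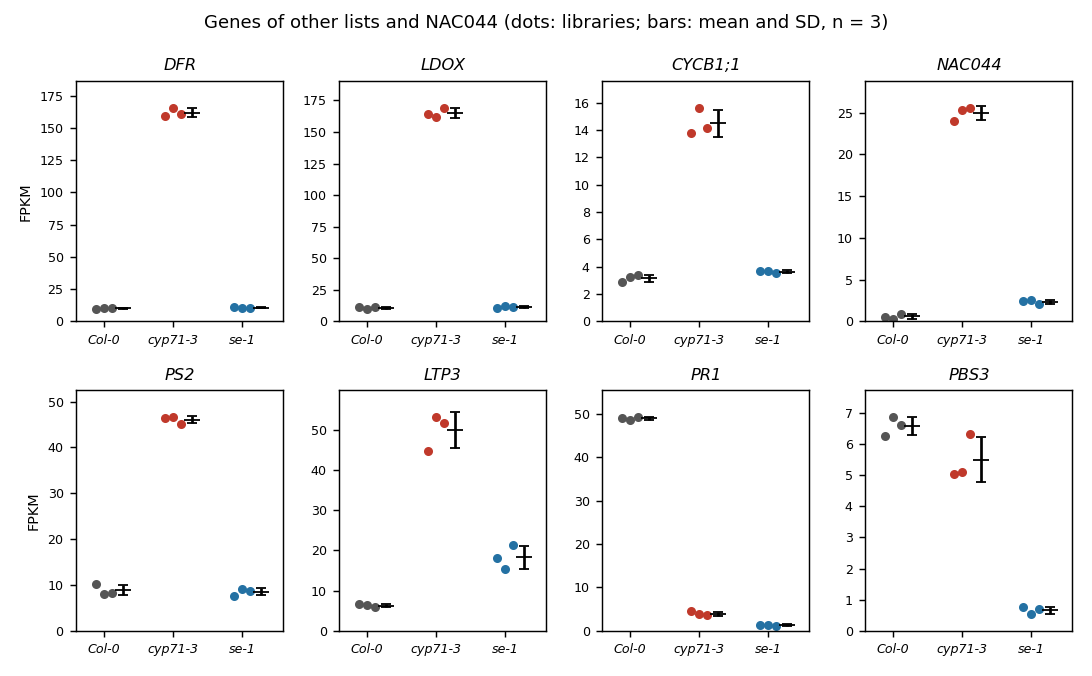
FPKM (vertical axes, from 0) of 8 genes in each library of Col-0, cyp71-3 and se-1; dots are libraries and bars give mean and SD, n = 3. DFR was at 10.2 FPKM in Col-0, 162 in cyp71-3 and 10.6 in se-1, and PBS3 at 6.57, 5.49 and 0.67.

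The calls of both mutants against Col-0 were then compared. In both, 2420 genes were higher and 2845 lower, while 679 were higher in cyp71-3 and lower in se-1 and 1000 the opposite. Independent lists of these sizes would share 1475 and 1576 genes in the same direction, and 1474 and 1577 in opposite directions. Simulated groups without any effect against the shared Col-0 libraries gave 0.06 same-direction genes on average. Without an effect almost no gene is called, so this count cannot show how far shared controls raise the overlap. The covariance of the log2 fold changes across genes was 0.0943, against 0.0103 in the simulation, a difference of 0.0841. The correlation across genes, which are not independent replicates, was 0.362, against 0.501 in the simulation. The simulated correlation follows from sharing the controls alone, so it does not show the mutants to be less alike than unrelated groups. Part of the excess over independent lists may come from the shared controls. Divided between the mutants as 1 and 2 libraries in all 6 ways, an alternative added after the data were seen, the Col-0 libraries gave 3610 to 4052 same-direction genes, against 1908 to 2148 for independent lists. The covariance was then 0.0773 to 0.0835, and the correlation was 0.279 to 0.307 without shared controls. The lone library was assumed to vary like the others.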

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

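The tests of other splits of the libraries, of miRNA families, of DNA damage genes and of translation and meristem genes were chosen after the results they bear on had been seen. The gene lists below were singled out because the direct test between cyp71-3 and se-1 found their effects to differ. As medians of the log2 difference, cyp71-3 minus se-1, miRNA targets gave -0.283 and tasiRNA precursors and targets -0.357. Salicylate defence gave 0.691, flavonoid and anthocyanin 1.8, cold and ABA 0.817 and phosphate starvation 0.982. Aliphatic glucosinolate genes gave 0.25, cell cycle genes 0.658 and iron deficiency genes -0.863. No list among these kept its call with an estimated correlation between genes.

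The counts of called genes cannot be set against enough other splits. Each comparison of 6 libraries has 10 splits into 3 and 3, so the share with as many calls cannot go below 0.1. In each comparison 1 of the 10 splits, the real one, gave as many. The real counts were 12148, 9633 and 11921, and the highest other split called 1, 2 and 1 genes. Every other split mixes both genotypes in each group, so the genotype difference enters the spread and few calls follow. Their low counts therefore do not measure how many calls arise without an effect.

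The first pattern is that miRNA targets were mostly higher in se-1 and moved both ways in cyp71-3. Library scaling is argued against, since the lower of the se-1 medians under quantile normalization and median centring was 0.275. Expression level and transcript length are argued against as well, since the median of 0.31 lay at percentile 100 of 10000 random lists matched on both, whose highest was 0.132. The random genes were drawn independently of each other, so the spread of their medians may be too narrow for targets that move by family. With an estimated correlation the list call in se-1 did not hold (camera adjusted p = 0.0726). Within cyp71-3, targets of one miRNA family moved alike more than random families of the same sizes would (permutation p = 0.00016, 69 targets in 16 families), which is consistent with the hypothesis that loss of CYP71 acts on some families and not on others. Family members are also related genes that may respond together for other reasons, and the same permutation test gave p = 0.00023 in se-1, so this stays open.

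The second pattern is that annotated miRNA genes were listed above 0 more often in se-1, with 82 values above 0 against 52 in Col-0, a ratio of 1.58 (95% exact interval 1.1 to 2.28, taking values as independent). Depth or retention of short fragments may account for part of it, since other non-coding genes of the same length range gave a ratio of 1.12 (1.02 to 1.24). The intervals overlap, so the explanations cannot be told apart. In an added look at other non-coding genes under 300 bp the ratio was 1.11 (0.881 to 1.41). Genes under 300 bp held 1.742% to 4.8751% of the FPKM sum in se-1 libraries and 3.3045% to 7.9935% in Col-0. These ranges overlap and do not show greater retention in se-1. Detections of miRNA genes did not follow relative depth alone. There were 28 in se-1 replicate 2 (depth 1.0154), 16 in Col-0 replicate 3 (1.2007) and 15 in cyp71-3 replicate 2 (1.351). The deepest library, se-1 replicate 3 (1.5928), had the most, 32. Accumulation of unprocessed precursors in se-1 remains an untested biological explanation.

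The third pattern is the rise of cell cycle genes in cyp71-3, where 22 of 25 were higher but the list call did not hold with an estimated correlation (adjusted p = 0.0562). Library scaling is argued against, with a lowest median of 0.865 under the 2 scalings. A larger share of young growing tissue stays open, since the higher median of translation and ribosome biogenesis was 0.023, while the meristem genes STM (2.79 to 5.27 FPKM), KNAT1 (8.69 to 11.07), KNAT2 (0.75 to 1.64) and KNAT6 (7.45 to 9.72) were called higher, as were the miRNA targets CUC1 (0.35 to 1.29) and GRF1 (5.64 to 12.76), all picked after their values were seen. In se-1, where the cell cycle median was 0.35, libraries held 3.98 to 4.17 FPKM of KNAT2, 1.76 to 2.25 of CUC1 and 12.15 to 13.82 of GRF1. Of the 6 tested targets of miR164, CUC1 among them, 1 was higher in cyp71-3 and 2 lower. A candidate explanation is a DNA damage response: a list of 16 such genes, written after NAC044 and the cyclins were seen and leaving both out, had 14 of 15 tested members higher in cyp71-3 (median 0.95, camera p = 7.27e-07, p = 0.00653 with an estimated correlation), among them BRCA1 (1.35 ± 0.08 SE) and WEE1 (1.38 ± 0.11). The p-values of the DNA damage list are not adjusted over lists. They cannot be set beside the adjusted p of the cell cycle list. The DNA damage list also rose in se-1 (9 of 15 higher, 1 lower, median 0.36, camera p = 0.00359, p = 0.0536 with an estimated correlation), and several of its genes vary with the cell cycle, so a rise in dividing cells stays open.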

How the results depend on the processing

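The alternatives that dropped genes under 300 bp or genes with overlapping groups, or split the Col-0 libraries, were chosen after the data were seen. Requiring a log2 fold change of at least 1 in addition left 1263 genes in cyp71-3 against Col-0, 675 in se-1 against Col-0, 1410 between the mutants and 191 in the same-direction overlap, by construction. All other alternatives kept these 4 counts within 1.5 times. Leaving out 1 library at a time gave 11159 to 12448, 8471 to 9599, 10828 to 11821 and 4565 to 5239. The median of miRNA targets ranged from -0.093 to -0.0614 in cyp71-3, 0.3 to 0.341 in se-1 and -0.315 to -0.244 between the mutants; under quantile normalization it was -0.015 in cyp71-3. With an estimated correlation the miRNA target calls ended in se-1 (median 0.31, camera adjusted p = 0.0726) and between the mutants (-0.283, 0.0523). The cause was not tested. With fry the list passed in cyp71-3 (median -0.0925, fry adjusted p = 0.00103), as did every list tested there except precursor and machinery genes. Unlike camera, fry does not set a list against the other genes. Under quantile normalization the photosynthesis median in cyp71-3 turned to 0.0187, while under median centring it was -0.262. With fry the flowering list in se-1 was called higher while its median was -0.0991. The causes were not tested. Calls by fry also ran against the median for flowering (0.315), salicylate defence (0.0141) and stomatal lineage (0.03) in cyp71-3, called lower, and for auxin early response in se-1 (-0.00235), called higher. Among the other lists and single genes, 42 results passed and 23 ceased to pass under an alternative in the same direction, 31 and 16 of them from fry and the estimated correlation. Leaving out a library ended a call in 4 cases, all of the MIR163 difference between the mutants, and added 3, all of heat shock genes in se-1. Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.137 to 0.043, others at -0.082 to 0.152. A replicate block called 11864, 9238 and 11572 genes. The planned count model was not run, since whole fragments were not recovered. Depth limits low and short genes most.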

Other observations

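The process terms below were chosen after the gene lists had been seen. Among 245 terms of the reference annotation with 10 to 500 tested genes, cell wall organization genes were higher in both mutants. In cyp71-3 18 of 20 were higher and 1 lower (median 0.95, camera adjusted p = 1.17e-05), and in se-1 14 were higher and 2 lower (median 0.67, camera adjusted p = 0.00027). Genes of microtubule-based movement were higher in cyp71-3 for 27 of 41 and lower for 8 (median 0.35, camera adjusted p = 0.00767). In se-1, genes of the innate immune response were lower for 33 of 59 and higher for 3 (median -0.27, camera adjusted p = 0.000568). Chloroplast organization genes were lower in se-1 for 22 of 30 and higher for 2 (median -0.25, camera adjusted p = 0.00027), and higher in cyp71-3 than in se-1 for 21 and lower for 1 (median 0.29, camera adjusted p = 0.000887). No term was called with an estimated correlation.

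By miRNA family, the 3 tested targets of miR398 had a median log2 fold change of -0.98 in cyp71-3 and 1.05 in se-1, and the 3 tested of the 4 listed for miR408 had -0.63 and 0.40. The 8 tested of the 11 listed for miR156 had -0.22 and 0.50. Of the 7 targets of miR169, 6 were called higher in cyp71-3 and none lower, and 5 were called higher and 1 lower in se-1. Of the 3 targets of miR171, 3 were called lower in cyp71-3 and 2 in se-1, where the other did not pass. Targets of miR172 had a median of 0.38 in cyp71-3 and -0.20 in se-1.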
